A study of Mus musculus with 22 samples.

How the data were processed

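The samples were 22 livers of male adiponectin-knockout mice, 3 to 8 months old, on a C57BL/6J background, taken at 6 times of a day with 12 h of light. Per the labels' protocols, RNA was extracted with TRIzol, and 100 ng per sample was amplified and labelled with biotin using the WT Plus kit for Clariom S mouse arrays. The deposited data give a log2 expression value per transcript cluster and array, rounded to 2 decimals. The base of the logarithm is not stated there; a range from about 2 to 20 without negative values was taken as log2, and every difference and fold here rests on that reading. Background correction, summarization, normalization, software and genome build of the authors are not given in the sources used here. The columns have nearly the same median and quartiles but are not identical in distribution, so some scaling between arrays was done before deposit. The data have no detection calls, and the lower quartile of an array lies near 3.8, so levels about there cannot be told from background. Arrays have no read depth; their number limits the precision.

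Groups follow the time in the sample labels: ZT2 (n = 4), ZT6 (n = 3), ZT10 (n = 4), ZT14 (n = 4), ZT18 (n = 3) and ZT22 (n = 4). The labels state 3 to 4 mice per time, and each array was taken as 1 mouse. The p-values measure the spread between these samples. The letters that tell the arrays of a time apart were not taken to pair them. The series labels also speak of wild-type mice, which were not analysed here. The lowest correlation between 2 arrays was 0.976 and the highest 0.994, and 0 pairs of arrays were identical.

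Of 22206 features 19572 had 1 gene symbol in the probe annotation, 2634 had none and 0 had several. The features named 19505 distinct genes, and all 19572 gene IDs were found in the mouse gene annotation (assembly GRCm38.p6), which changed 0 symbols. Features without a symbol were tested but are not named. A gene with several features is represented by the one with the highest mean.

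Analysis used R 4.3.3 with limma 3.58.1 and the package data.table (version 1.17.8). Models were fitted with lmFit and eBayes to all features, with no filter on dim ones, and p-values were adjusted by the Benjamini-Hochberg method over all features with a threshold of 0.05. The 24 h rhythm was the moderated F test of a cosine and a sine of 24 h, and the fold span from trough to peak is 2 raised to the doubled amplitude. The 12 h component was the F test of a 12 h cosine and sine added to that model. The contrast of light and dark (the mean of ZT2, ZT6 and ZT10 minus the mean of ZT14, ZT18 and ZT22) and the contrasts ZT2 minus ZT14, ZT6 minus ZT18 and ZT10 minus ZT22 came from a model of the 6 time means on all arrays. Differences carry limma's standard error, and group means carry the SD.

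The comparisons, gene lists, rule for named genes and all but 2 alternatives were fixed before the data were examined. The 31 lists cover the core clock, PAR bZIP factors and targets, heat shock, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, gluconeogenesis and glycogen, bile acids, drug metabolism, amino acids, glucocorticoid response, unfolded protein response, ribosomal proteins, ribosome biogenesis, respiratory chain, adiponectin receptors and AMPK, insulin and IGF, autophagy, acute phase, cell cycle, male-biased genes, clock- or feeding-driven genes, and markers of Kupffer cells, sinusoidal endothelium, stellate cells, cholangiocytes, lymphocytes, neutrophils, erythroid cells, adipocytes and pancreatic acinar cells. In the light and dark contrast lists were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry. The share of rhythmic members was tested with Fisher's exact test against all other named features. Both families were adjusted over the lists.

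Named genes were, for the 24 h rhythm, the 3 of largest amplitude with a peak in each 4 h window and all core clock genes; up to 3 genes of lowest adjusted p in each other list; the 6 of largest 12 h amplitude; the 5 of largest light and dark difference in each direction whose means did not interleave; the 3 of largest difference in each direction of the other contrasts; and Adipoq. This gave 118 genes. Predicted genes were left out. Tff3 and other genes given with the arrays that stood apart were chosen after their values were seen, as were members of lists named only as higher in one phase or at one time.

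Alternatives were quantile normalization, centring of arrays, features above the median level, eBayes with a trend and robust prior, arrayWeights, the replicate letter as a block, each array left out in turn, ranks, a threshold of 0.01, a 1.5-fold minimum, an F test of any difference among times, the 24 h test beside 12 h terms, an unmoderated F test, each time left out, light and dark as 2 plain groups, and fits of 2 times alone. The alternatives added after seeing the data were the first principal component of the residuals as a covariate, and the 5 arrays with the highest values of that component, which are also the 5 with high Tff3, left out. Leaving these out keeps 1 array at ZT6 (ZT6a), so values of that setting that use ZT6 lean on it. The clock genes of ZT6a gave a time of 8.6 h, nearer ZT10 than its label. Changes in values that use ZT6 thus cannot be told from an effect of the time of ZT6a.

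The scripts were tested on simulated data of 22206 features with known changes. Recovery of effects of 0.25, 0.5 and 1 log2 units was 3.08%, 76.1% and 98.5% for the 24 h amplitude, 7.69%, 75.8% and 96.4% for the 12 h amplitude, 1.56%, 34.2% and 95.0% for light and dark, 1.75%, 5.56% and 54.9% for ZT2 and ZT14, 0%, 1.54% and 32.9% for ZT6 and ZT18, and 0%, 8.70% and 59.4% for ZT10 and ZT22. These effects were placed only in features above the median level, so recovery in dimmer ones is not known. The simulated data gave 28 to 125 calls per comparison, against 252 to 1691 in the real data, or 4 for the 12 h component. The adjustment of p-values depends on how many features change, so recovery in the real data may differ. A simulated list shifted by 0.25 was called and 0 of the other lists were. Genes were simulated independently, so this does not show how often preset camera calls lists of correlated genes by chance. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.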

Results

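Transcripts were measured around the day in livers of male mice that lack adiponectin, a hormone released by fat cells. The mice lived in 12 h of light and 12 h of darkness with free access to chow, and livers were taken at 4 h intervals. RNA of each of 22 livers was hybridised to its own Clariom S array. Times are given as zeitgeber time (ZT), hours after lights on, so ZT2, ZT6 and ZT10 fall in the light phase and ZT14, ZT18 and ZT22 in the dark phase. There were 4 arrays at ZT2, 3 at ZT6, 4 at ZT10, 4 at ZT14, 3 at ZT18 and 4 at ZT22, and the arrays of a time are told apart by letters (ZT2a). The number of arrays limits the precision. Wild-type livers were not analysed here, so the comparisons ask how liver transcripts differ between times of day in the knockout, and none of them measures an effect of losing adiponectin. Values are on a log2 scale.

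The targeted gene, Adipoq, lay near the low end of the scale in every array, between 3.30 and 4.69 with a median of 3.62. Its mean stood at percentile 23.5 of all features, with 14 arrays at or below the lower quartile of their array. It was not called for a 24 h rhythm (adjusted p = 0.289), but a change at such levels could hardly be seen. The low level checks the genotype little, since liver makes little adiponectin, no wild-type array stands beside it, and whether the probes lie in the deleted part of the gene is not known. Another feature of the arrays concerns several gene groups below. Tff3, which encodes a secreted trefoil peptide, measured 10.35 in ZT6b, 11.60 in ZT6c, 13.26 in ZT14b, 13.63 in ZT14d and 11.42 in ZT22a, and between 2.31 and 4.73 in the other 17 arrays. Among the genes of the comparisons, Igfbp1, Cdkn1a, Chka, Noct, Nampt, Cbs, Gpt2, Bnip3, Rrs1, Cd5l and Cpt1a lay higher in these 5 than in every other array of their time, and Thrsp, Nat8f5 and Herpud1 lower. These are 14 of the 118 genes whose rhythms were tried under other settings, of which 18 were set apart in this way where chance alone gives 3.28. Over all 19505 named genes 953 lay higher and 678 lower. By list, the genes higher and lower were 10 and 0 of 24 in amino acid metabolism, 9 and 0 of 28 among ribosomal proteins, 0 and 5 of 17 in bile acids, 5 and 3 of 19 in drug metabolism, 5 and 0 of 18 in the insulin axis, 5 and 0 of 20 in the cell cycle, 4 and 3 of 18 in fatty acid synthesis, 0 and 5 of 16 among male-biased genes, and 0 and 0 of 14 in the core clock. The arrays were picked by their values, so these counts are no test.

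**Figure D1:**
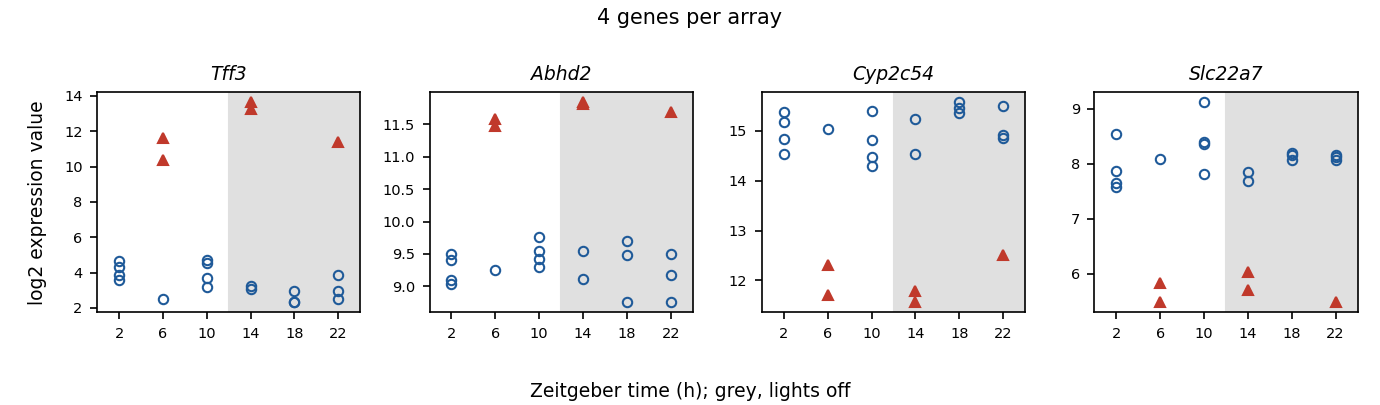
Log2 expression value (vertical axes) of Tff3, Abhd2, Cyp2c54 and Slc22a7 in each array against zeitgeber time in hours (horizontal axes; grey, lights off); red triangles are the 5 Tff3-high arrays and blue circles the other 17. Tff3 is 10.35 to 13.63 in the former and 2.31 to 4.73 in the latter, and the genes and arrays shown were chosen after their values were seen.

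The clock ran at large amplitude in these livers: all 14 measured core clock genes had a 24 h rhythm. Arntl, which encodes the activator BMAL1, peaked at ZT22.9 ± 0.245 h (SE, n = 22) with a 33.7-fold span from trough to peak, and its mean went from 5.30 ± 0.51 (SD, n = 4) at ZT10 to 10.55 ± 0.15 (SD, n = 4) at ZT22. Its partners Clock and Npas2 peaked at ZT23.5 and ZT23.9, with fitted spans of 3.49-fold and 13.4-fold. Nr1d1, a repressor of Arntl, had a peak at ZT6.83 ± 0.201 h and a 118-fold span, and Nr1d2 followed at ZT8.99 with 11.9-fold. The negative-limb genes peaked later in a sequence, Ciart at ZT12.3 (33.0-fold), Per3 at ZT12.7 (21.1-fold), Per1 at ZT13.4 (9.01-fold), Per2 at ZT15.1 (19.0-fold) and Cry1 at ZT19.3 (7.72-fold). Cry2, Bhlhe40, Bhlhe41 and Rora had spans from 1.77-fold in Rora to 3.82-fold in Bhlhe41, and the call for Rora was lost without the 5 Tff3-high arrays. The fitted spans of Ciart, Npas2 and Per1 are uncertain, since their lowest time means (4.04, 4.31 and 4.33) lie close to the level that cannot be told from background. Adjusted p-values of the 24 h test ranged from 9.22e-12 for Ciart to 0.00969 for Rora.

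**Figure D2:**
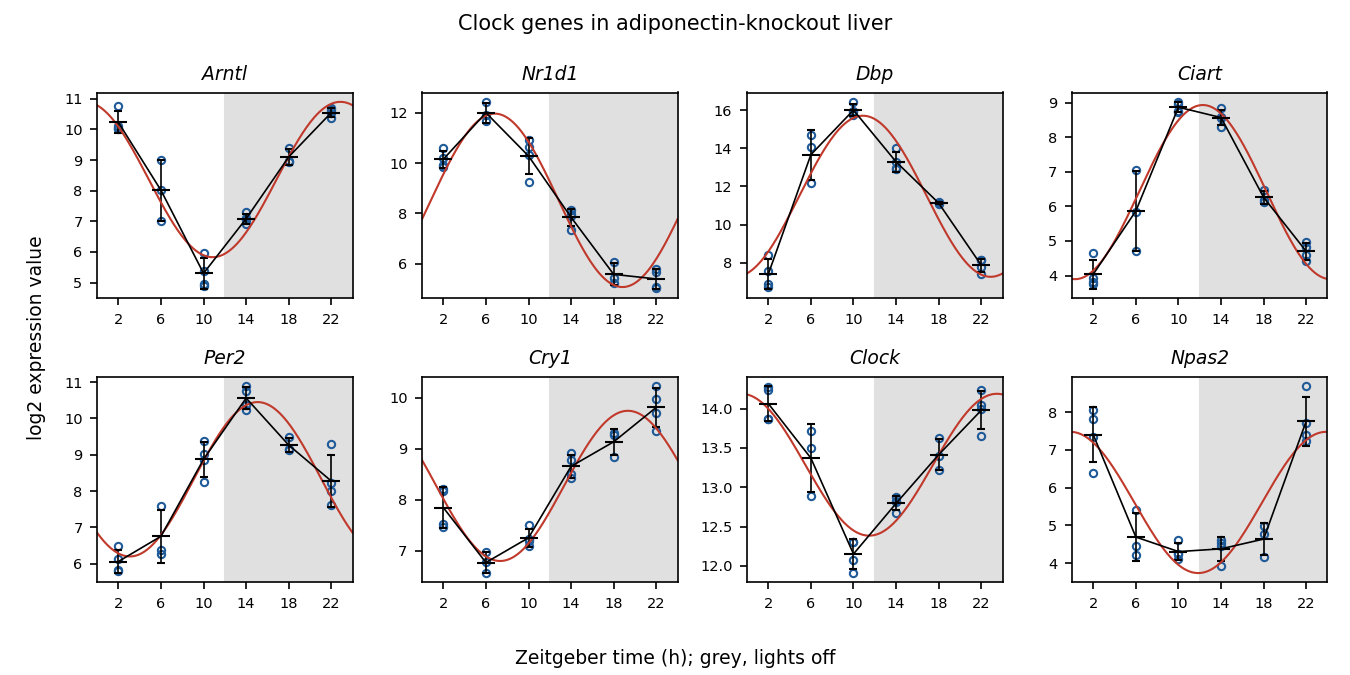
Log2 expression value (vertical axes) of 8 clock and clock-output genes against zeitgeber time in hours (horizontal axes; grey, lights off); open circles are single arrays, black bars the mean ± SD of 3 or 4 arrays, red lines the fitted 24 h curve. Arntl is highest at ZT22 (10.55) and lowest at ZT10 (5.30), while Nr1d1 is highest at ZT6 (12.00).

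Genes driven by the clock were rhythmic as well. Dbp, a transcription factor that is a direct output of the clock, went from 7.41 ± 0.77 at ZT2 to 15.998 ± 0.30 at ZT10 (SD, n = 4 each), a fitted 348-fold span. Of the list of PAR bZIP factors and their targets, 7 of 10 genes were rhythmic (8 adjusted over the list alone), with Tef peaking at ZT11.5 (a fitted 4.55-fold, with a trough at background) and Nfil3, their competitor at DNA, at ZT22.8 (4.84-fold). Of 15 genes known to follow the clock or feeding, 13 were rhythmic, both over all features and adjusted over the list alone. Among these were Usp2 (67.6-fold, ZT13.9), Elovl3, an elongase of very long fatty acids (58.8-fold, ZT23.5), Rgs16 (29.4-fold, ZT9.18), Noct (20.5-fold, ZT13.0), Cdkn1a (16.1-fold, ZT20.3) and Tspan4 (5.27-fold, ZT15.6). The fitted spans of Usp2, Rgs16 and Cdkn1a are uncertain, since their lowest time means (4.02, 4.18 and 3.60) lie about the level that cannot be told from background. Wee1, a cell cycle kinase under clock control, peaked at ZT13.4 with a 12.6-fold span. Of the 20 measured cell cycle genes 4 were rhythmic (7 adjusted over the list alone), including Ccne1 (2.87-fold, ZT11.6) and Tk1 (2.11-fold, ZT17.6).

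Genes of sterol and bile acid metabolism were rhythmic in part. Of 17 measured cholesterol synthesis genes 12 were rhythmic, and all 17 when adjusted over the list alone, with a mean peak at ZT22.8. Hmgcs1, which makes the precursor of mevalonate, peaked at ZT1.39 (5.53-fold), Pmvk at ZT21.3 (3.26-fold) and Insig1, which restrains the pathway, at ZT20.0 (2.50-fold). Of 17 genes of bile acid synthesis and transport 8 were rhythmic (10 adjusted over the list alone). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose from 12.89 ± 0.73 at ZT2 to 16.36 ± 0.64 at ZT10 (SD, n = 4 each) and had a fitted peak at ZT14.6, whereas Abcb11, the bile salt export pump, and Hsd3b7 peaked at ZT2.17 and ZT1.95.

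Genes of carbohydrate and fat metabolism were rhythmic with peaks in both phases. Of 15 genes of gluconeogenesis and glycogen 10 were rhythmic, also when adjusted over the list alone. The glycogen-targeting subunits Ppp1r3b and Ppp1r3c peaked at ZT18.5 (12.5-fold) and ZT21.3 (32.5-fold), and Gys2, the liver glycogen synthase, peaked earlier, at ZT13.0 (5.71-fold). Of 18 genes of fatty acid and triglyceride synthesis 10 were rhythmic (13 adjusted over the list alone), among them Elovl6 (6.08-fold, ZT14.4), Agpat2 (3.20-fold, ZT19.9), Thrsp (12.0-fold, ZT15.9) and Lpin1, the phosphatidate phosphatase (7.58-fold, ZT12.0). Of 19 genes of fatty acid oxidation and ketogenesis 5 were rhythmic (11 adjusted over the list alone). Cpt1a, which admits fatty acids to mitochondria, peaked at ZT10.2 (3.03-fold), Ppara at ZT12.3 (2.68-fold) and Pdk4 at ZT22.4 (4.22-fold). Of 24 genes of amino acid and one-carbon metabolism 7 were rhythmic (9 adjusted over the list alone), including Nampt, which makes NAD precursor (8.87-fold, ZT14.5), Gpt2 (2.36-fold, ZT15.3) and Cbs (2.72-fold, ZT3.33).

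**Figure D3:**
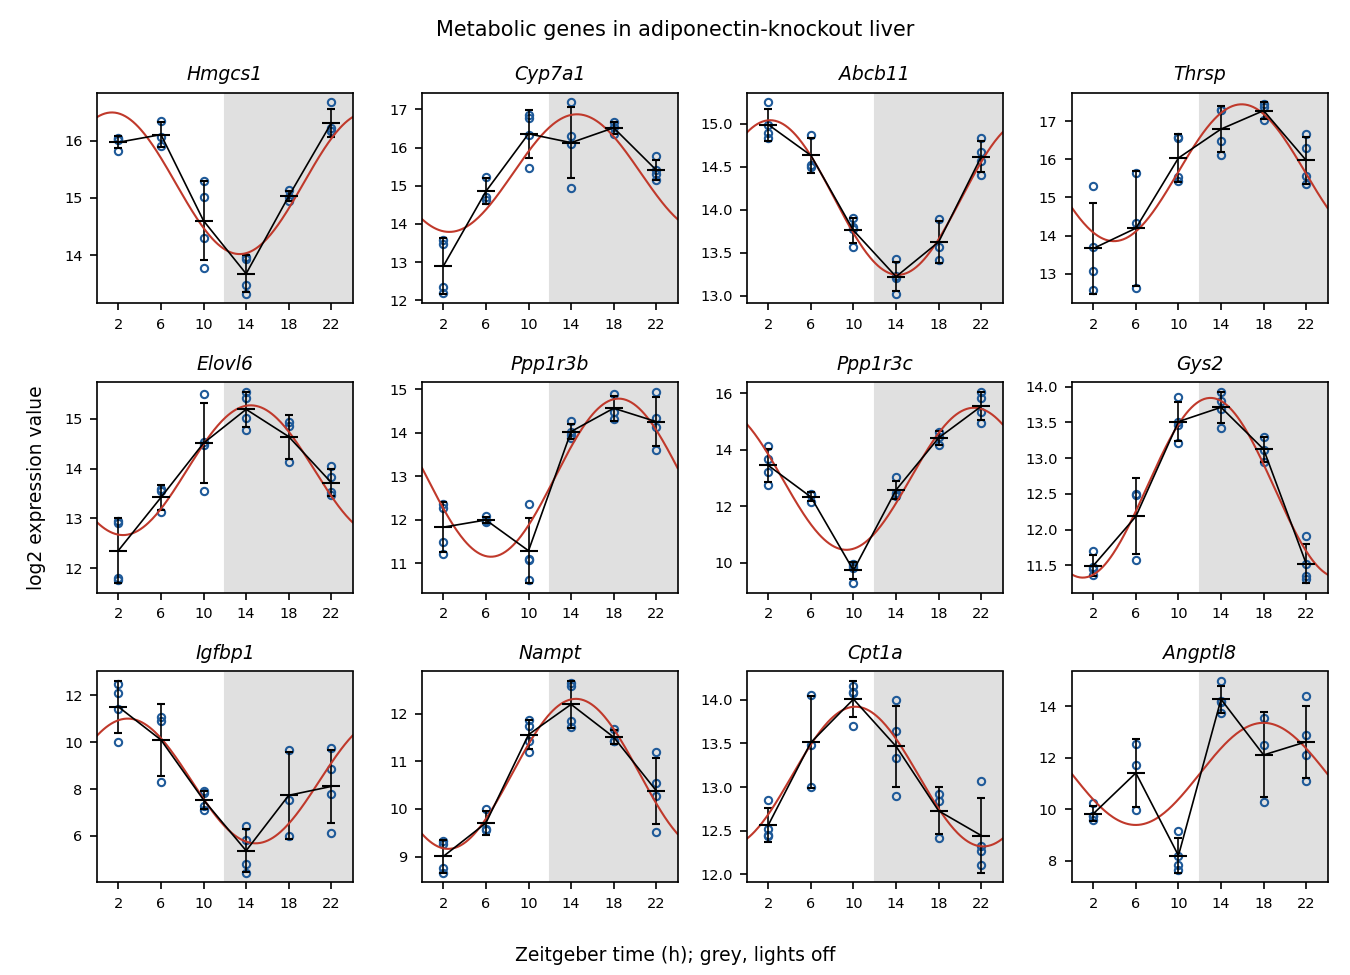
Log2 expression value (vertical axes) of 12 metabolic genes against zeitgeber time in hours (horizontal axes; grey, lights off); open circles are single arrays, black bars the mean ± SD of 3 or 4 arrays, red lines the fitted 24 h curve. Ppp1r3c is lowest at ZT10 (9.73) and highest at ZT22 (15.53), and Cyp7a1 is lowest at ZT2 (12.89).

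Hormone and stress responses were rhythmic in part. Of 14 glucocorticoid-responsive genes 8 were rhythmic (9 adjusted over the list alone), with Fkbp5 at ZT14.2 (6.50-fold), Tsc22d3 at ZT17.7 (8.26-fold) and the metallothionein Mt1 at ZT10.4 (16.5-fold). The fitted peak of Mt1 is uncertain, since its mean was highest at ZT14 (14.165) and its ZT6 arrays lay far apart (SD 2.39). Of 12 cold-inducible and heat-shock genes 6 were rhythmic (10 adjusted over the list alone), such as Rbm3 (2.98-fold, ZT12.7), Hsph1 (5.67-fold, ZT16.8) and Hspa1a (2.19-fold, ZT13.1). Of 18 genes of the insulin and IGF axis 4 were rhythmic, as many as when adjusted over the list alone. Igfbp1, a circulating binding protein that insulin represses, had a 39.8-fold span with a peak at ZT2.88, Irs2 peaked at ZT2.58 (3.93-fold) and Pik3r1 at ZT14.2 (2.27-fold). Of 15 genes of adiponectin receptors and AMPK signalling 2 were rhythmic, over all features and adjusted over the list alone: Ppara and Appl1, an adaptor of the adiponectin receptors (1.76-fold, ZT1.65, adjusted p = 0.0374). The call of Appl1 was lost in most omissions of a single array. Prkaa2, a catalytic subunit of AMPK, was not called (adjusted p = 0.0915). Of 17 autophagy and lysosome genes 4 were rhythmic (8 adjusted over the list alone), with Ulk1, the kinase that starts autophagy, at ZT7.48 (3.53-fold), Gabarapl1 at ZT6.32 (3.58-fold) and Bnip3 at ZT13.0 (3.12-fold). Of 19 acute phase and complement genes 5 were rhythmic (9 adjusted over the list alone), including Saa1 (3.35-fold, ZT11.6), Apcs (1.86-fold, ZT5.13) and Fga (1.43-fold, ZT3.82).

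Genes of protein folding, translation, respiration and drug metabolism were tested too. In the unfolded protein response 3 of 20 genes were rhythmic, over all features and adjusted over the list alone: Herpud1 (3.11-fold, ZT12.4), Dnajb9 (2.49-fold, ZT14.9) and Trib3 (1.61-fold, ZT7.48). In ribosome biogenesis 5 of 23 were rhythmic (13 adjusted over the list alone), with Nop58 (2.11-fold), Rrs1 (1.81-fold) and Nop14 (1.56-fold) peaking between ZT15.3 and ZT17.1. Rps15 was the 1 rhythmic gene of 28 ribosomal protein genes (1.64-fold, ZT19.4), and adjusting over the list alone gave 1 as well, while Rpl3 and Rpl6 did not pass (adjusted p = 0.0750 and 0.127). Of 25 respiratory chain genes limma called 0, and 0 adjusted over the list alone. The nearest were Sdhc (adjusted p = 0.0737), Sdhb (0.0870) and Cyc1 (0.193). In drug and xenobiotic metabolism 2 of 19 genes were rhythmic (4 adjusted over the list alone), Cyp2a4 (9.39-fold, ZT15.6) and the monooxygenase Fmo5 (2.30-fold, ZT16.3), and Sult1d1 missed the threshold (adjusted p = 0.0582).

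Over the whole array, limma's F test called 1691 of 22206 features rhythmic over 24 h (7.62%), or 1501 named genes. The median span of these features was 1.89-fold, and 702 spanned at least 2-fold. In the windows up to ZT8 the largest amplitudes besides Nr1d1 and Igfbp1 were those of Egr1, an immediate early factor (21.5-fold, ZT3.51), Rnf125, a ubiquitin ligase (19.3-fold, ZT0.543), the mitochondrial carrier Slc25a30 (13.8-fold, ZT4.53) and Clec2h (9.13-fold, ZT5.26). In the dark phase Angptl8, a secreted regulator of lipoprotein lipase (15.6-fold, ZT18.0), and Nat8f5 (9.66-fold, ZT18.6) stood beside the glycogen genes. The fitted peak of Angptl8 is uncertain, since its mean was highest at ZT14 (14.26), with 12.10 at ZT18 and 12.61 at ZT22. More features peaked in the dark than in the light, 308, 349 and 366 in the windows after ZT12, ZT16 and ZT20 against 262, 245 and 161 after ZT0, ZT4 and ZT8. Peaks were counted by window on the deposited scaling alone. In the contrast of light and dark, the light share of calls went from 38.4% to 46.7% with quantile normalization and to 38.6% with centring. Scaling may thus bear on the lean of the peaks too. Brighter features were called more often, 13.6% of those above the median level against 1.62% of the rest. Against a background of 7.70% of named features, 12 of 31 lists held more rhythmic genes in Fisher's exact test (two-sided, adjusted over the lists). These were the core clock (adjusted p = 7.49e-15), the clock- or feeding-driven genes (4.44e-12), cholesterol synthesis (1.84e-09), gluconeogenesis and glycogen (1.15e-07), fatty acid synthesis (1.08e-06), PAR bZIP factors (7.95e-06), glucocorticoid response (1.05e-05), bile acids (6.05e-05), heat shock (0.000436), amino acids (0.00526), fatty acid oxidation (0.0324) and the acute phase (0.0324). The Fisher background holds bright and dim features alike, and the lists were not matched to it in level. A share above it may thus partly reflect level. Fatty acid oxidation and the acute phase held 26.3% each, against 13.6% of all features above the median level. Fisher's test also takes genes as independent. Members of a list can move together (estimated correlation 0.359 in cholesterol synthesis), and some genes stand in several lists. Its p-values may thus be too small. With ranks in place of values 1065 features were called, and 830 at a threshold of 0.01. Calls lost when some single array was left out were those of Angptl8, Appl1, Cd5l, Dnajb9, Foxq1, Nop14, Nop58, S100a9, Stab2 and Tk1, and calls gained were those of Cd79b, Cidec, Clec4f, Clec4g, Gpam, Kdr, Prkaa2, Rpl3, Sdhc, Sox9 and Sult1d1. Those of Angptl8, Appl1 and Foxq1 were each lost in most of these omissions. Without the 5 Tff3-high arrays 1305 features were called, with Rora, Trib3, Dnajb9, Rrs1, Nop14, Nop58, Appl1, Apcs, Fga and S100a9 lost and Clec4f, Dcn, Gpam, Hsd3b5, Rpl3, Sox9 and Tm4sf4 gained.

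**Figure D4:**
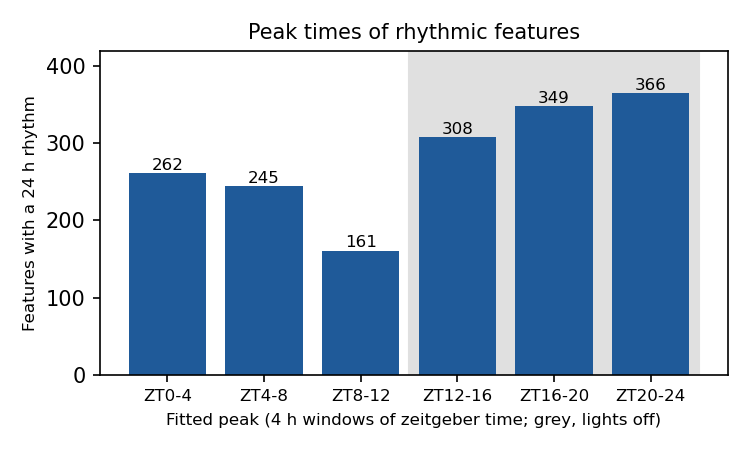
Number of features with a 24 h rhythm (vertical axis) by fitted peak in 4 h windows of zeitgeber time (horizontal axis; grey, lights off). The window from ZT20 holds 366 features and the window from ZT8 holds 161.

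Few transcripts were called for a 12 h component beside the 24 h term. Such a component can also come from a 24 h rhythm that is not shaped like a cosine. A call alone thus does not show a separate 12 h rhythm. Dbp had a 12 h amplitude of 1.24 ± 0.17 (SE, n = 22) on the log2 scale beside its larger 24 h term, with means of 7.41 ± 0.77 at ZT2 (SD, n = 4) and 13.66 ± 1.30 at ZT6 (SD, n = 3). The means of Dbp rose to 15.998 at ZT10 and fell at each later time, to 7.87 at ZT22. Wee1 had a 12 h amplitude of 0.66 ± 0.09. Its means also rose and fell once, with 7.01 at ZT2, 11.085 at ZT10 and 8.525 at ZT22. For Dbp and Wee1 a 12 h rhythm thus cannot be told from the shape of the 24 h rhythm. Gpam, which catalyses the first step of glycerolipid synthesis, had a 12 h amplitude of 0.53 ± 0.08, larger than its 24 h amplitude of 0.43 ± 0.13, with means of 15.73 ± 0.19 at ZT6 and 16.37 ± 0.17 at ZT18 (SD, n = 3 each) against 15.01 ± 0.27 at ZT10 and 15.12 ± 0.14 at ZT14 (SD, n = 4 each). These and a feature without a gene symbol here were the 4 features limma called (adjusted p = 0.00865 for Dbp, 0.0118 for Wee1 and 0.0320 for Gpam). At an unadjusted p under 0.05 there were 1678. The count ranged from 1 to 15 over the alternative settings and from 2 to 16 when single arrays were left out, and it was 10 without the 5 Tff3-high arrays, where Gpam was lost. The call of Gpam was also lost when any 1 of 11 arrays was left out (adjusted p = 0.119 without ZT18b) and with the replicate letter as a block, where Wee1 was lost too.

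Between the phases, Nr1d1 was 4.53 ± 0.18 log2 units (SE) higher in the light than in the dark. The mitochondrial carriers Slc25a30 (2.45 ± 0.36) and Slc25a47 (1.61 ± 0.16), Clec2h (2.21 ± 0.35) and the forkhead factor Foxq1 (1.90 ± 0.46) were also higher in the light. Higher in the dark were Angptl8, with a light minus dark difference of −3.19 ± 0.37 (SE), the glycogen subunit Ppp1r3b (−2.58 ± 0.19), the cell cycle inhibitor Cdkn1a (−2.56 ± 0.46), the glucocorticoid-induced Tsc22d3 (−2.13 ± 0.25) and the acetyltransferase Nat8f5 (−2.12 ± 0.20). In each of these genes the 3 light means lay on one side of the 3 dark means, but without the 5 Tff3-high arrays the means of Cdkn1a (5.74 at ZT2, 5.21 at ZT14) and Slc25a47 (13.79 at ZT2, 13.91 at ZT14) interleaved. The difference of Cdkn1a is a lower bound, with ZT10 at background. Adjusted p-values from limma ran from 2.05e-14 for Nr1d1 to 0.0159 for Foxq1. In all 1170 features differed, 449 higher in the light and 721 higher in the dark. The count fell to 700 with arrays taken as 2 groups without time and to 511 with a 1.5-fold minimum. Without the 5 Tff3-high arrays ZT6 holds ZT6a alone, which by its clock genes lay nearer ZT10 than ZT6. Light and dark values of that setting, here and for the lists, lean on that array. With limma's trend and robust prior the call of Foxq1 was lost, here and for the 24 h rhythm.

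Most gene lists that moved between the phases ranked towards the dark. Features above the median level leaned that way as a whole, with a median light minus dark difference of −0.0425 against 0.013 over all features. Part of the ranking of lists of bright genes may reflect this. Camera called 11 lists with those features alone and 11 with quantile normalization, against 15 as reported. In the heat-shock list Hsph1 (−1.61 ± 0.25) and 4 other genes were higher in the dark and Cirbp, the cold-inducible RNA-binding protein, was the 1 gene higher in the light (7 dark and 1 light adjusted over the list alone; camera adjusted p = 4.11e-06, and adjusted p = 0.0570 with an estimated correlation). In fatty acid and triglyceride synthesis 6 genes were higher in the dark and 0 in the light, among them Thrsp (−2.05 ± 0.32) and Elovl6 (−1.09 ± 0.20), with 8 and 1 adjusted over the list alone (adjusted p = 4.11e-06, and adjusted p = 0.0876 with an estimated correlation). In drug metabolism the 3 genes called, Cyp2a4 (−1.79 ± 0.29), Fmo5 (−0.79 ± 0.10) and Sult1d1 (−0.59 ± 0.17), were higher in the dark, 5 adjusted over the list alone (adjusted p = 7.43e-05, and adjusted p = 0.0857 with an estimated correlation). Of the clock- or feeding-driven genes 5 were higher in the dark and Rgs16 in the light, as many adjusted over the list alone (adjusted p = 0.000806, and adjusted p = 0.0570 with an estimated correlation). Of the glucocorticoid-responsive genes 5 were higher in the dark, Fkbp5 (−1.02 ± 0.17) among them, and 1 in the light (6 and 1 adjusted over the list alone; adjusted p = 0.0112, and adjusted p = 0.163 with an estimated correlation).

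Genes of translation, respiration and protein folding also ranked towards the dark as lists. Ribosome biogenesis had 4 genes higher in the dark, with Nop58 at −0.79 ± 0.15, and 0 in the light (10 and 2 adjusted over the list alone; adjusted p = 0.000806, and adjusted p = 0.163 with an estimated correlation). Among the ribosomal proteins Rps15 (−0.46 ± 0.10) and Rpl3 (−0.39 ± 0.11) were higher in the dark, 2 also adjusted over the list alone (adjusted p = 0.000200, and adjusted p = 0.422 with an estimated correlation). The median of that list was −0.175 with all arrays and −0.104 without the 5 Tff3-high arrays (adjusted p = 0.00968). In the respiratory chain Sdhc (−0.39 ± 0.11) was the 1 gene called and 0 were called adjusted over the list alone. The list's median was −0.14 (adjusted p = 0.00132, and adjusted p = 0.364 with an estimated correlation). With quantile normalization the median was −0.07 and the list was not called (camera adjusted p = 0.0605). In the unfolded protein response Trib3 was called, higher in the light, and adjusting over the list alone gave 7 genes higher in the dark and 2 in the light (adjusted p = 0.0206 towards the dark, and adjusted p = 0.581 with an estimated correlation).

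Further lists ranked towards the dark. Of the core clock genes Arntl, Cry1, Cry2, Per1 and Per2 were higher in the dark and Nr1d1 and Nr1d2 in the light (8 and 3 adjusted over the list alone; adjusted p = 0.0112, adjusted p = 0.201 with an estimated correlation, and 0.385 without the 5 Tff3-high arrays). In gluconeogenesis and glycogen 3 genes were higher in the dark and 2 in the light (5 and 2 adjusted over the list alone; adjusted p = 0.0123, and adjusted p = 0.164 with an estimated correlation). In cholesterol synthesis Insig1 (−0.78 ± 0.13), Pmvk (−0.83 ± 0.18) and 2 other genes were higher in the dark and Hmgcs1 (0.55 ± 0.15) in the light (6 and 3 adjusted over the list alone; adjusted p = 0.0262, and adjusted p = 0.581 with an estimated correlation). In amino acid metabolism Nampt (−1.27 ± 0.17), Gpt2 (−0.67 ± 0.12) and 2 others were higher in the dark and Cbs (0.66 ± 0.15) in the light (5 and 1 adjusted over the list alone; adjusted p = 0.0355, and adjusted p = 0.581 with an estimated correlation). With quantile normalization the p-values of the last 3 lists became 0.0510, 0.0991 and 0.136, and those of the respiratory chain and the unfolded protein response 0.0605 and 0.1004. Without the 5 Tff3-high arrays, where ZT6 rests on ZT6a alone, the medians of the last 3 lists were −0.103, 0.051 and −0.035. With all arrays they were −0.096, −0.223 and −0.081, so the median of cholesterol synthesis changed sign. With ZT6 on 1 array this does not show a turn of that list to the light.

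Autophagy and lysosome genes ranked towards the light, with Gabarapl1 (1.31 ± 0.19), Ulk1 (1.15 ± 0.13) and 1 other gene higher in the light and 0 in the dark (4 and 0 adjusted over the list alone; adjusted p = 0.0161, and adjusted p = 0.163 with an estimated correlation). Not past the threshold as lists were bile acids (4 genes higher in the light, 2 in the dark; 4 and 3 adjusted over the list alone; adjusted p = 0.369), the insulin axis (2 and 0; 3 and 1; adjusted p = 0.710), fatty acid oxidation (1 and 0; 2 and 2; adjusted p = 0.972), adiponectin receptors and AMPK (0 and 0; 0 and 0; adjusted p = 0.972), the cell cycle (0 and 3; 1 and 5; adjusted p = 0.0909), PAR bZIP factors (1 and 4; 1 and 4; adjusted p = 0.388) and the acute phase (2 and 0; 3 and 1; adjusted p = 0.0674, and 0.0113 with quantile normalization). The tests of the PAR bZIP list and of fatty acid oxidation opposed their medians in sign, since the former had a median of 0.02 and a test towards the dark, and the latter a median of −0.03 and a test towards the light. In total camera called 15 of 31 lists, 13 towards the dark and 2 towards the light, and 0 with an estimated correlation. The rotation test fry called 9.

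The earliest light time was set against the time 12 h later. At ZT2 Igfbp1 stood at 11.51 ± 1.10 against 5.37 ± 0.91 at ZT14 (SD, n = 4 each), a difference of 6.13 ± 0.74 (SE), and all 4 ZT2 arrays lay above all 4 ZT14 arrays. Elovl3 (4.85 ± 0.35) and Rnf125 (4.68 ± 0.32) were also higher at ZT2, as were Irs2 (2.13 ± 0.38) and the bile acid genes Hsd3b7 (2.44 ± 0.25) and Abcb11 (1.77 ± 0.16). Higher at ZT14 were Usp2 (−6.05 ± 0.52), Noct (−5.92 ± 0.78), Dbp (−5.88 ± 0.39), Cyp7a1 (−3.23 ± 0.37), Nampt (−3.19 ± 0.28) and Gys2 (−2.21 ± 0.20). The difference of Usp2 is a lower bound, with ZT2 at background. Limma called 948 features, 459 higher at ZT2 and 489 higher at ZT14 (48.4% at ZT2, but 56.6% without the 5 Tff3-high arrays, 54.4% without ZT2d and 39.6% without ZT14a), with adjusted p = 6.98e-06 for Igfbp1 and 4.08e-08 for Usp2. The count was 514 without the 5 Tff3-high arrays, 589 without ZT14b alone, 627 without ZT14d alone and 556 with the other times left out of the fit. Igfbp1 measured 5.82 in ZT14b and 6.42 in ZT14d against 4.43 and 4.82 in the other 2 arrays of that time, and Noct 12.56 and 12.57 against 9.85 and 9.16.

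In the middle of each phase, ZT6 against ZT18, Nr1d1 differed by 6.42 ± 0.34 (SE), from 12.00 ± 0.40 at ZT6 to 5.58 ± 0.44 at ZT18 (SD, n = 3 each). Egr1 (3.92 ± 0.93) and Mt1 (3.21 ± 0.74) were also higher at ZT6, and Nat8f5 (−3.49 ± 0.39), Thrsp (−3.08 ± 0.60), the linker histone H1f2 (−3.07 ± 0.48), Ppp1r3b (−2.57 ± 0.36) and Tsc22d3 (−2.41 ± 0.47) higher at ZT18. Limma called 252 features, 87 higher at ZT6 and 165 higher at ZT18 (adjusted p = 1.67e-11 for Nr1d1, 0.0382 for Egr1 and 0.0319 for Mt1). At ZT6, 2 of the 3 arrays were Tff3-high, and Mt1 measured 13.17 and 15.30 in these against 10.53 in ZT6a. It was also higher in ZT22a (11.65 against 9.28 to 9.91). At ZT14 it was not higher in the Tff3-high arrays (14.16 and 13.47 against 14.22 and 14.81). The clock genes of ZT6a gave a time of 8.6 h, so at ZT6 its time and the Tff3 split cannot be told apart. Without the 5 Tff3-high arrays the count was 59, with ZT6 down to 1 array whose spread is assumed to be that of the other times, and Egr1, Mt1, Thrsp and H1f2 were no longer called. The differences then were 5.19 for Egr1 and −2.997 for H1f2, about as large as or larger than with all arrays, and 0.74 for Mt1 and −1.64 for Thrsp, nearer 0 than with all arrays. The calls of Egr1 and Mt1 were also lost with the trend and robust prior, and those of Egr1, Mt1 and Thrsp when some single array was left out. It was 440 without ZT6a, 82 without ZT6b, 106, 87 and 91 without ZT18a, ZT18b and ZT18c, 417 with features above the median level, 458 with the first residual component as a covariate and 109 with the other times left out, and with quantile normalization 45.1% of calls were higher at ZT6 against 34.5%. Without the 5 Tff3-high arrays the balance turned, with 54.2% higher at ZT6.

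Before each change of lighting, ZT10 against ZT22, Dbp was 8.12 ± 0.39 (SE) higher at ZT10, with means of 15.998 ± 0.30 and 7.87 ± 0.34 (SD, n = 4 each). Rgs16 (5.14 ± 0.63), Nr1d1 (4.88 ± 0.30), Ciart (4.17 ± 0.31), Lpin1 (2.78 ± 0.43) and Cpt1a (1.56 ± 0.24) were also higher at ZT10. Higher at ZT22 were Ppp1r3c (−5.80 ± 0.26), Chka, which starts phosphatidylcholine synthesis (−5.43 ± 0.45), Cdkn1a (−5.34 ± 0.76), Arntl (−5.25 ± 0.29), Elovl3 (−5.25 ± 0.35) and Hmgcs1 (−1.70 ± 0.24). The differences of Chka and Cdkn1a (ZT10 at background) and of Rgs16 (ZT22 at background) are lower bounds. Of the 17 cholesterol synthesis genes 11 were higher at ZT22 and 0 at ZT10. Limma called 733 features, 255 higher at ZT10 and 478 higher at ZT22 (adjusted p = 9.00e-13 for Dbp and 4.10e-13 for Ppp1r3c).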

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

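The single-value test was planned. Each of the 118 genes chosen by the rule for named genes was checked at each time with 4 arrays for a single array far from the other 3, by Dixon's test at the 95% level. Of 472 such groups 22 had one (4.66%), and chance gives about 1 in 20.

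Among clock genes and their outputs, Per1 measured 6.41 in ZT14a against 7.87 to 8.17 in the other arrays of its time, Per3 5.73 in ZT22b against 7.06 to 7.31, Arntl 10.77 in ZT2c against 10.01 to 10.10, and Usp2 6.47 in ZT22a against 7.14 to 7.27. Among metabolic genes, Lpin1 measured 11.30 in ZT22d against 9.56 to 9.75, Ppara 12.25 in ZT2c against 11.31 to 11.41, and Ppp1r3c 13.03 in ZT14c against 12.36 to 12.47. Hmgcs1 was set apart in 2 arrays, with 15.81 in ZT2d against 16.01 to 16.04 and 16.67 in ZT22a against 16.16 to 16.22. Nat8f5 measured 11.46 in ZT14c against 10.61 to 10.67, and Hsd3b5 15.83 in ZT2d against 16.98 to 17.08. At ZT10, Prkaa2 measured 13.46 in ZT10b against 13.83 to 13.90 and Ulk1 8.30 in ZT10a against 8.74 to 8.82.

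Array ZT10c held 4 of the values: Nop58 at 7.96 against 8.41 to 8.48, Sdhc at 12.25 against 11.73 to 11.75, Sdhb at 13.78 against 14.04 to 14.07, and Tk1 at 5.80 against 6.07 to 6.11. Nop14 measured 9.72 in ZT22a against 9.99 to 10.04. Among marker genes of other cells, Tm4sf4 measured 11.52 in ZT2c against 12.49 to 12.69 and 11.25 in ZT10d against 11.78 to 11.87. Cldn7 measured 3.08 in ZT14a against 3.51 to 3.55, and Cela3b 4.70 in that array against 4.14 to 4.19, levels at which background cannot be told from signal. Wrong times on the labels were tested from the clock genes; no other explanation was tested for these single values.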

How the results depend on the processing

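The settings with the first residual component as a covariate and with the 5 Tff3-high arrays left out were chosen after seeing the data, and the others were planned. The settings were run for the 24 h amplitudes of 118 genes (106 with features above the median level), the 12 h amplitudes of 3 and 28 differences between times, and not for the other differences given. Of the 28 differences 0 changed sign. Counts within 1.5 times of those reported came from quantile normalization and centring for every comparison. The rhythm count became 1065 with ranks and 830 at a threshold of 0.01, and stayed between 1146 and 1460 with a time left out. For the 12 h component the count was 10 with the trend and robust prior, 15 with arrayWeights, 12 with the covariate, 10 without the 5 arrays and 1 at a threshold of 0.01. Light against dark gave 700 as 2 groups, 511 with the 1.5-fold minimum and 617 without the 5 arrays. ZT2 against ZT14 gave 556 alone and 514 without the 5 arrays, and ZT6 against ZT18 gave 109 alone, 417 above the median level, 458 with the covariate and 59 without the 5 arrays. Lists called were 0 with an estimated correlation and 9 with fry. For the 24 h rhythm, quantile normalization lost Stab2, the trend and robust prior lost Angptl8, Dnajb9 and Foxq1 and gained Sult1d1, Rpl3, Sdhc, Sdhb, Clec4g and Kdr, and arrayWeights lost Appl1 and S100a9 and gained Sult1d1, Rpl3, Clec4f, Clec4g and Gpam. Features above the median level gained Sult1d1, Rpl3, Sdhc, Sdhb, Clec4g, Kdr and Gpam, and the covariate gained Sult1d1. The cause of the shifts under settings other than the covariate was not tested. With the covariate 1691 of the 2039 rhythmic features, and without the 5 arrays 1068 of 1305, were also among those reported. The covariate was drawn from residuals about the time means, so it left amplitudes and differences unchanged and acted on the estimated spread alone. The calls it kept and added are thus no test of the results.

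Leaving out single arrays gave 1464 to 1691 rhythmic features, 2 to 16 for the 12 h component, 825 to 1427 for light and dark, 589 to 1018 for ZT2 and ZT14, 82 to 440 for ZT6 and ZT18, 532 to 796 for ZT10 and ZT22, and 13 to 16 lists. ZT2 against ZT14 moved by over 1.5 times without ZT14b (589) or ZT14d (627), and ZT6 against ZT18 without ZT6a (440), ZT6b (82), ZT18a (106), ZT18b (87) or ZT18c (91). The 12 h count was 16 without ZT2d, 10 without ZT6c, 8 without ZT22b, 7 without ZT10d or ZT14c, and 2 without ZT2a, ZT14a, ZT18a, ZT18b, ZT18c, ZT22c or ZT22d.

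With the replicate letter as a block, 1527 features were rhythmic and the 12 h count was 1, with Wee1 and Gpam lost, as were the 24 h calls of Angptl8, Cd5l and Foxq1; no other call among those run changed. The letters gave no sign of pairing. Deviations of arrays with the same letter at different times had a mean correlation of −0.00889, 3 of 51 pairs were above 0.1, and 5 of 22 arrays correlated best with their own letter.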

Other observations

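The test for a linked region, the covariate and the omission of the 5 Tff3-high arrays were chosen after their results or the data were seen; the tests for intestinal and female-type expression were prompted by the Tff3 values, with their bounds set before their results were seen. Some markers of other liver cells differed between times. Of 12 Kupffer cell and macrophage markers 1 was rhythmic, Cd5l, a secreted scavenger-receptor protein (2.04-fold, ZT6.46), also adjusted over the list alone, and the list ranked towards the light (camera adjusted p = 0.0436, and adjusted p = 0.581 with an estimated correlation). Clec4f and Lyz2 were not rhythmic (adjusted p = 0.102 and 0.289), but Clec4f was called without ZT6b (adjusted p = 0.0182) and was higher at ZT2 than at ZT14 by 0.96 ± 0.18 (SE). Of 11 markers of sinusoidal endothelium Stab2 was rhythmic (1.71-fold, ZT23.3), 4 adjusted over the list alone, and Clec4g and Kdr missed the threshold (adjusted p = 0.0574 and 0.0589), though each was called without some single arrays. Stab2 (0.805 ± 0.23), Kdr (0.71 ± 0.18) and Dnase1l3 (0.94 ± 0.26) were higher at ZT2 than at ZT14. The difference of Stab2 leans on the Tff3-high ZT14b (7.96) and ZT14d (7.89), against 8.59 in ZT14a and 8.91 in ZT14c. Kdr measured 10.80 and 10.50 in the former and 10.61 and 10.55 in the latter. That list did not differ between the phases (adjusted p = 0.268), though it ranked towards the dark without the 5 Tff3-high arrays (0.00883). Of 9 neutrophil markers S100a9 was rhythmic (1.90-fold, ZT4.77), 1 also adjusted over the list alone (list adjusted p = 0.588).

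In 6 other marker lists limma called 0 genes rhythmic, and 0 adjusted over each list alone: stellate cells (12 genes, lowest adjusted p for Dcn, 0.214; list adjusted p = 0.147), cholangiocytes (9, Sox9, 0.0866; 0.224), lymphocytes (10, Cd79b, 0.0917; 0.420), erythroid cells (3, Bpgm, 0.851; 0.542), adipocytes (10, Plin4, 0.128; 0.393) and pancreatic acinar cells (13, Cpa1, 0.269; 0.676). With single arrays left out Sox9 was called without ZT6b, ZT14b or ZT18b (adjusted p = 0.0449 to 0.0487), Cd79b without ZT18a (0.0389) and Cidec without ZT6b (0.0448), and without the 5 Tff3-high arrays Sox9, Tm4sf4 and Dcn were called. Sox9, a transcription factor of bile duct cells, was higher at ZT22 than at ZT10 (ZT10 minus ZT22, −1.875 ± 0.35). Between the phases Cd79b passed the test (0.48 ± 0.13, SE), but its means of 3.33 to 4.33 cannot be told from background. Cidec and Plin4, which coat lipid droplets and are made by hepatocytes too, were higher at ZT14 than at ZT2 (ZT2 minus ZT14, −2.96 ± 0.78 and −1.29 ± 0.34). For neutrophils and pancreatic acinar cells the median opposed the mean and the test in sign. Of 16 male-biased liver genes 1 was rhythmic, Elovl3, also adjusted over the list alone (list adjusted p = 0.147 between the phases), and Hsd3b5 was not (adjusted p = 0.304). The Y-linked gene Eif2s3y lay between 11.05 and 12.05 in all arrays.

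The first residual component held 16.7% of the variance left by the time means, and the 5 Tff3-high arrays had its highest values. Beside Tff3, the steroid hydroxylase Cyp17a1 measured 9.65 to 11.41 in these arrays and 5.39 to 8.20 in the other 17, the lipid hydrolase Abhd2 11.48 to 11.84 and 8.75 to 9.76, and Got1, an aminotransferase, 15.01 to 16.14 and 11.36 to 13.75. Below the other arrays were the cytochromes Cyp2c54 (11.56 to 12.51 and 14.29 to 15.57), Cyp2c37 (11.00 to 12.55 and 13.70 to 15.61) and Cyp2c50 (14.67 to 15.33 and 16.76 to 17.66), and the transporter Slc22a7 (5.48 to 6.03 and 7.57 to 9.11). The arrays were picked by such values, so the contrast is no test.

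Several readings of these arrays were set against the tables. Intestinal tissue is argued against, since 0 of 22 intestinal markers were higher in all 5 arrays. One linked genomic region holding the separated genes is argued against, since the highest chromosome ratio was 1.31 (chromosome 13), though 1 gene acting on others elsewhere may still differ between mice. Female-type liver expression cannot be told apart: 5.26% of 19 female-biased genes were higher, but 31.3% of 16 male-biased genes, Hsd3b5 and Slco1a1 among them, were lower. Age within the stated range, feeding state and litter were not tested.

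For arrays other than ZT6a, wrong times on the labels are argued against as a cause of outlying clock values. Predicted from 16 clock genes of the other arrays, the time of each array lay a median of 0.6 h from its label and at most 2.6 h, in ZT6a (8.6 h predicted). All arrays but ZT6a lay within 2 h, and 0 arrays lay over 4 h away. Times are 4 h apart, so the 4 h bound could hardly show a swap with a neighbouring time. ZT6a lay nearer ZT10 than its label, so a wrong or late time is left open for it.

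More features were higher in the dark (721) than in the light (449), so the light share of calls was 38.4%. Scaling between arrays may account for part of this imbalance, since quantile normalization gave 46.7%, but centring of arrays left the share at 38.6%. Without the 5 Tff3-high arrays the share was 43.0%, under the 45% set beforehand. ZT6 then rests on ZT6a alone, so how far those arrays account for the imbalance is not settled. A larger set of dark-phase genes remains open.

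In 6 comparisons 1 of the splits run, the real one, gave as many calls. For those other than the 12 h component, this argues against chance as the source of the whole count. The other splits mix arrays of different times, which widens the spread within groups and lowers their counts. They are thus no estimate of the number of false calls. Over 100 assignments of arrays to times the real and the highest other count were 1691 and 1 for the 24 h rhythm, 4 and 2 for the 12 h component, 1170 and 34 for light and dark, and 15 and 11 for the lists. The other assignments called a median of 4 lists, and 92 of 99 called at least 1, so preset camera calls lists by chance, and 0 of the 15 passed with an estimated correlation. The 12 h count rests on few features, with 1 left under the replicate block and 2 without some single arrays. The reassignments also broke the 24 h rhythm, so they do not test the 12 h term beside it, and nothing is concluded from them about that term. Over 35 splits the real and the highest other count were 948 and 3 for ZT2 and ZT14, and 733 and 1 for ZT10 and ZT22. For ZT6 and ZT18 the 10 splits are too few for a share under 0.05, and the counts were 252 and 0.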
